A study of Mus musculus with 6 samples.

How the data were processed

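Total RNA from the skin of 6 mice of the inbred strain C3H/HeJ was measured on 1 oligonucleotide array per mouse. The labels put 3 mice in a group with alopecia areata, sampled in affected alopecic skin, and 3 mice in an unaffected group. The series design text states that each array came from a different mouse, so the spread between arrays of a group holds the spread between animals. Per the labels' protocols, RNA was purified with a Qiagen miRNeasy kit and on-column DNase digestion, and was labelled with biotin by a 3' IVT Express kit, which copies transcripts from their 3' end. No batch, scan, litter, age or body site is given in the sources used here.

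The authors deposited log2 values, 1 per probe set and array, and the submitters' processing notes name RMA, a method that corrects background, normalizes arrays to each other and summarises the probes of a probe set. The version and software of RMA are not given in the sources used here. Such values are relative: a difference between groups in total RNA per cell is removed by the normalization between arrays, and a signal near background has compressed differences, so that fold differences of dim genes are understated. The deposited values ran from 3.07 to 14.92, the array medians lay between 6.11 and 6.17, and no value was missing. They were used as deposited, without further normalization. An array has no read depth, and the number of arrays, 3 per group, limits the precision.

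The table held 45101 probe sets, of which 64 were control probe sets. A platform annotation table listed 35890 probe sets; 34945 had 1 gene symbol and 932 had several, while 9160 probe sets other than controls had no symbol there. Symbols were updated through the gene identifiers of the RefSeq annotation of GRCm38.p6, which matched for 34741 probe sets; the symbol of the annotation table was kept for 204. The authors' genome build is not given in the sources used here, so the annotation served for names and no coordinates are given. Probe sets with several symbols or none were left out of the gene test. For each gene the probe set with the highest mean over the 6 arrays was taken, which gave 18193 genes, 9010 of them with more than 1 probe set. Dim probe sets were not filtered.

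Alopecic and unaffected skin were compared gene by gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a moderated two-sided test on the log2 values, alopecic minus unaffected). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. All adjusted p-values of single genes in the text come from this fit unless another test is named. "Rose" and "fell" refer to genes past that threshold, and other differences are given as values. Errors of differences are standard errors of the fit, and errors of group means are standard deviations over 3 arrays.

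Before the data were examined, 38 gene lists were fixed: lymphocyte, myeloid and mast cell markers, interferon responses, antigen presentation, cytokines, chemokines and signalling, layers of the hair follicle, melanocytes, the cell cycle, the other tissues of skin, and stress and clock genes. They had 742 entries for 721 different genes, of which 632 were matched to a measured symbol. The lists with at least 3 measured genes were tested with camera in limma, which compares a list with all other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 36 lists. The list of ligands of the receptor NKG2D had too few measured genes, and the sex-linked list served as a check of the animals. For each list the count of members past the threshold is given over all genes and adjusted over the list alone. Camera was repeated with the correlation estimated for each list, and fry, a rotation test of whether the genes of a list move one way on balance without comparing it with other genes, was run beside it.

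The genes named in the text follow a rule fixed before the data were examined. It takes up to 10 genes with the largest rise and up to 10 with the largest fall, among those past the threshold whose alopecic arrays all lay on one side of the unaffected arrays. It adds up to 4 members of each list past the threshold or, where none passed, the 2 with the highest mean. It also takes 22 genes chosen for the disease, 20 of which had a probe set with a single symbol; the others are not analysed here. The rule gave 98 genes. Genes named outside it are said to have been chosen after their values were seen.

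Array similarity was described by principal components and by Pearson correlations between arrays across genes. RNA quality was checked by the 3' minus 5' log2 difference of the beta-actin and Gapdh control probe sets, with an exact two-sided permutation test over 20 assignments, whose smallest possible p is 0.1. No pair of arrays shared more than 92 identical probe set values, so no array was counted as deposited more than once. The fit was tested on data simulated for the comparison of alopecic with unaffected skin over 18193 genes, of which 200 were changed. It recovered 34.3% of genes changed 2-fold, 67.2% of those changed 4-fold and 87.9% of those changed 16-fold, with 3 false calls among 129. In simulated lists, camera called 5 of 5 shifted lists and 1 of 28 unshifted lists. The simulated genes varied independently of each other. In the data the estimated correlations ran from -0.171 in the erythroid list to 0.968 in the keratin-associated protein list. The simulation therefore does not show how often camera errs with correlated genes.

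The alternatives fixed in advance were other settings of limma, a plain per-gene test, quantile normalization, centring of the arrays, filters on dim genes, other choices of probe sets, a minimum fold of 2, array weights, the replicate number as a block, other list tests, and leaving out each array in turn. A fit with the mean of the hair shaft keratin list as a covariate, the emphasis on the values without unaffected replicate 3, and camera with an estimated correlation with each array left out were added after the data were seen. For 1 test, 10000 random lists of 27 genes were drawn from 20 bins of mean expression to match the interferon gamma response list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.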

Results

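Gene expression was compared between alopecic skin of C3H/HeJ mice with alopecia areata and skin of unaffected C3H/HeJ mice. Alopecia areata is an autoimmune hair loss in which lymphocytes surround growing hair follicles, and C3H/HeJ is an inbred strain in which it can arise spontaneously. Each group held 3 mice, with 1 array per mouse, and 18193 genes were measured as log2 RMA values. The comparison asked which genes and cell types differed between affected and unaffected skin.

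The mean Pearson correlation across genes, which are not independent replicates, was 0.9795 over the 3 pairs of alopecic arrays and 0.9387 over the 3 pairs of unaffected arrays. Unaffected replicates 1 and 2 correlated at 0.981, and their correlations with unaffected replicate 3 were 0.9294 and 0.9056. Between the groups it averaged 0.9557 (SD 0.0211 over 9 pairs). The first principal component held 52.7% of the variance and set unaffected replicate 3, at 99.28, apart from the other arrays, which lay between -39.57 and -6.14. The second component held 21.4% and separated the groups, with alopecic arrays between 24.54 and 29.85 and unaffected arrays between -44.97 and -12.05. Unaffected replicate 3 carried 42.2% of the squared deviations from the group means, and the next highest array, unaffected replicate 2, carried 21.0%. The 3' minus 5' difference of the beta-actin control probe sets was 0.970 ± 0.439 (SD, n = 3) in alopecic and 0.707 ± 0.463 (SD, n = 3) in unaffected skin, a difference of 0.263 (exact two-sided permutation p = 0.6). For Gapdh it was 0.306 ± 0.302 and 0.125 ± 0.196 (SD, n = 3 each), a difference of 0.181 (exact two-sided permutation p = 0.4). Xist, the RNA of the inactive X chromosome, had a log2 value of 13.17 ± 0.06 in alopecic and 13.11 ± 0.27 in unaffected skin, and the Y-linked Kdm5d had 4.49 ± 0.11 and 4.58 ± 0.03 (SD, n = 3 each). None of the 4 measured sex-linked genes passed the test (median log2 difference -0.01).

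**Figure D1:**
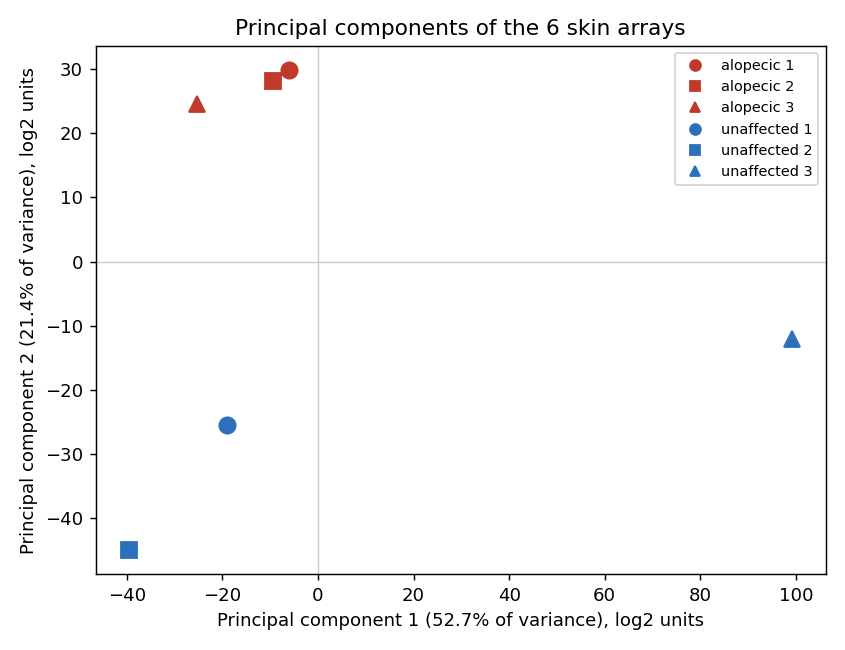
Principal component scores of the 6 arrays, in log2 units, over all genes, with component 1 on the x axis and component 2 on the y axis. Each point is 1 mouse; unaffected replicate 3 lies at 99.28 on component 1, and all alopecic arrays lie above all unaffected arrays on component 2.

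Of 18193 genes, 48 rose and 2 fell in alopecic skin, and 17 of those that rose belonged to the fixed list of the interferon gamma response. Ubd, a ubiquitin-like protein induced by interferon gamma, rose with a log2 difference of 7.08 (SE 0.69), or 136-fold (adjusted p = 0.0301). Without alopecic replicate 2 its rise was 238-fold (adjusted p = 0.00566), and with any other array left out it missed the threshold (adjusted p from 0.0873 to 0.193). The T cell attracting chemokines Cxcl9, Cxcl11 and Cxcl10 rose 74.98-fold, 53.3-fold and 37.6-fold. Cxcl9 had a log2 value of 12.89 ± 0.60 in alopecic and 6.67 ± 0.50 in unaffected skin (SD, n = 3 each), a difference of 6.23 (SE 0.38, adjusted p = 0.0091). The guanylate-binding protein Gbp8 rose 33.1-fold, the immunity-related GTPase Iigp1 25.4-fold, the T cell membrane protein Ms4a4b 23.3-fold, Oasl2 of the oligoadenylate synthetase family 23.1-fold, the GTPase Igtp 21.1-fold and Gbp6 20.2-fold. These folds are those of the brightest probe set of each gene. For Cxcl9, Cxcl11 and Ms4a4b a dimmer second probe set had smaller log2 differences, of 3.27, 1.82 and 0.32. For Iigp1 and Gbp6 the second probe set had larger ones, of 5.11 and 4.65. The genes that fell were Krt24, an epithelial keratin, with a log2 difference of -2.57 (SE 0.28, adjusted p = 0.0466), and Serpinb6e, a serine protease inhibitor, at -1.37 (SE 0.13, adjusted p = 0.0275). Neither passed in any of the 6 fits with 1 array left out. In all 12 of these genes the 3 alopecic arrays lay on one side of the 3 unaffected arrays, which the rule for naming them required. In 11 of the 48 genes that rose, Ubd, Cxcl11, Gbp8, Ms4a4b, Ifng and Car9 among them, the unaffected mean lay below the lowest array median of 6.11. Such dim signals have compressed RMA differences, and no detection calls were used here. Their folds are therefore not exact ratios, and the order of the largest folds is not fixed.

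Ifng, which encodes interferon gamma itself, rose 4.71-fold on the RMA scale, from a dim log2 value of 4.75 ± 0.19 in unaffected to 6.99 ± 0.45 in alopecic skin (SD, n = 3 each; adjusted p = 0.0494). Of the 50 changed genes, 27 belonged to a fixed list by matched symbol. For 22 of the 50 the arrays held further probe sets, 35 in all, of which 31 differed in the same direction, 24 of them with an unadjusted p under 0.05. Over all 18193 genes, 1301 had an unadjusted limma p under 0.05, 873 of them higher and 428 lower, where chance alone gives a share of 0.05. The number of lower genes did not exceed what that share gives in 1 direction. In 13.1% of genes the groups did not overlap, against 10% by chance. The number of changed genes depended on single arrays: it was 33 without alopecic replicate 1, 14 without alopecic replicate 2, 17 without alopecic replicate 3, 7 without unaffected replicate 1, 4 without unaffected replicate 2 and 39 without unaffected replicate 3. The 4 genes that passed in each of these 6 fits were Igtp and Gbp6 and, chosen after their values were seen, Gbp2 and Gbp2b.

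The fixed gene lists were tested next. By camera 17 of 36 lists were shifted, 14 to higher and 3 to lower values in alopecic skin. Of 10 splits of the arrays into 3 and 3, 7, the real one among them, gave at least as many lists. The count of lists by camera was therefore not particular to the real grouping. With an estimated correlation between the genes of a list none passed (smallest adjusted p = 0.165), and 7 had an unadjusted p under 0.05 in that test. That test was repeated with each array left out, as chosen after seeing the data; the interferon gamma response list passed without alopecic replicate 1 (adjusted p = 0.031), and no other list passed in any of these 6 sets of arrays. By fry 7 lists passed, all of them higher, namely those of the interferon gamma response, the type I interferon response, MHC class I presentation, cytotoxic lymphocytes, chemokines, common gamma chain cytokines and receptors, and regulatory T cells with T cell inhibitory receptors.

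**Figure D2:**
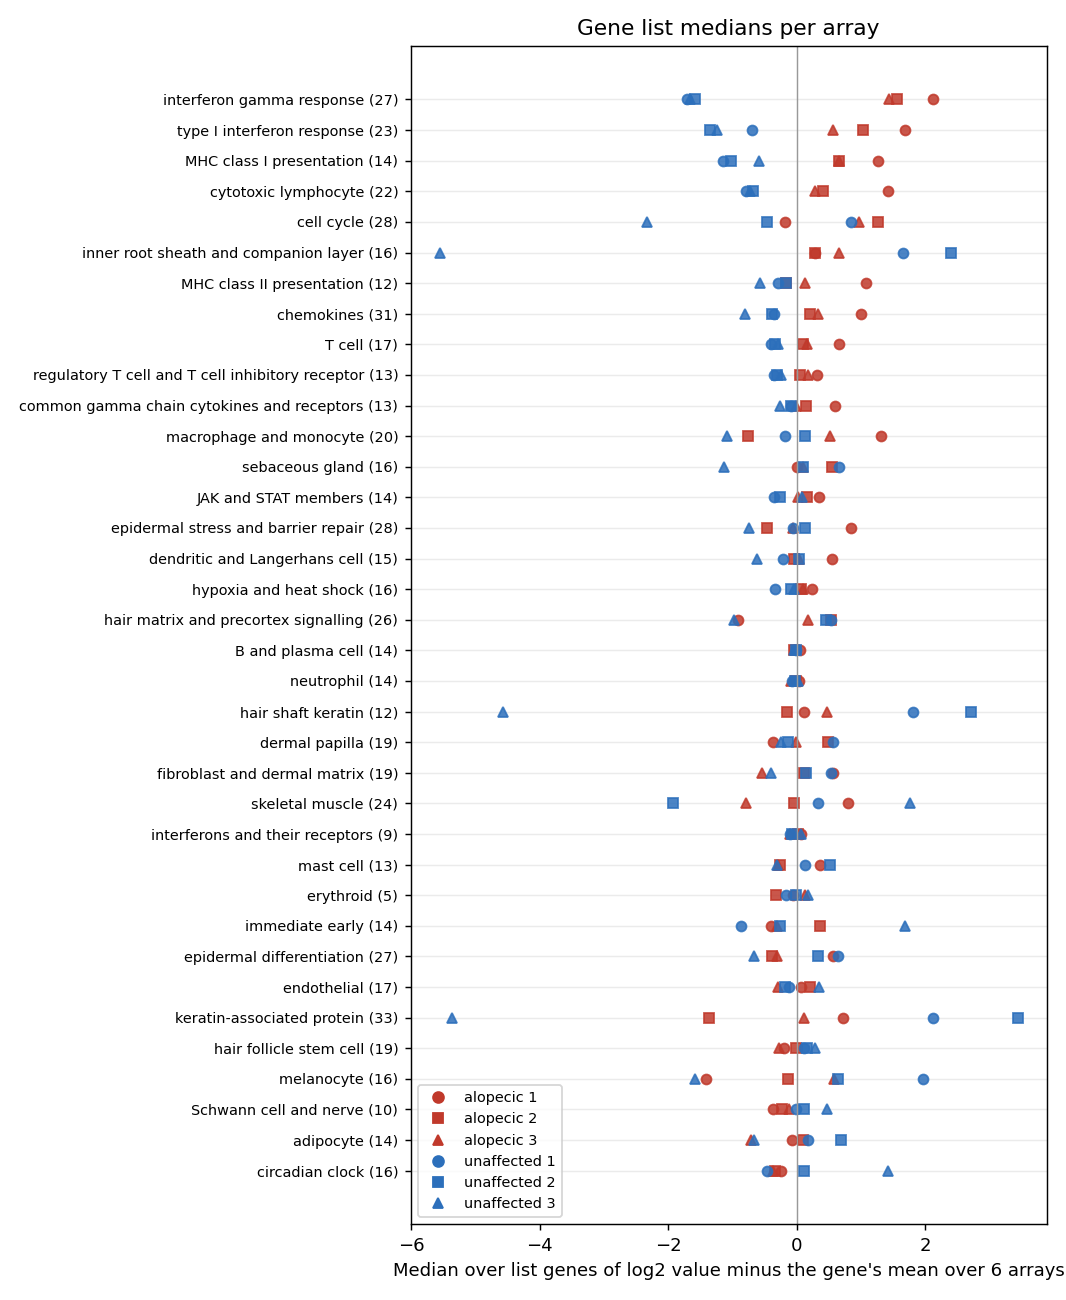
Median over the genes of each tested list of the log2 value minus the gene's mean over 6 arrays, on the x axis, with 1 row per list, the number of measured genes in brackets and 1 point per array. In the interferon gamma response list the alopecic arrays lie between 1.44 and 2.13 and the unaffected arrays between -1.70 and -1.57, while in the hair shaft keratin list unaffected replicate 3 lies at -4.57.

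The interferon gamma response list was higher as a whole. Of its 27 measured genes 17 rose, and all 27 rose when adjusted over the list alone. The median log2 difference was 3.07, or 8.41-fold, and each of the 27 genes was higher in every alopecic array than in every unaffected array (camera adjusted p = 5.23e-62, adjusted p = 0.165 with an estimated correlation, fry adjusted p = 0.00239). The type I interferon response list had a median of 2.19, or 4.57-fold. Of its 23 genes matched to a measured symbol, 6 rose over all genes tested and 23 when adjusted over the list alone (adjusted p = 0.165 with an estimated correlation). The entry Rigi was not matched to its earlier symbol Ddx58. Ddx58, chosen after its values were seen, rose 2.98-fold and is outside these counts. The largest rises in the list were those of Oasl2, of the receptor transporter Rtp4 at 11.3-fold, of the membrane protein Bst2, which tethers virus particles, at 9.80-fold, and of the oligoadenylate synthetase Oas1a at 8.65-fold. The MHC class I presentation list had a median of 1.78, or 3.43-fold, with all 14 measured genes higher in every alopecic array (adjusted p = 0.165 with an estimated correlation). The 3 members that rose were the immunoproteasome subunits Psmb9, at 6.06-fold, and Psmb10, at 5.06-fold, and the peptide transporter subunit Tap2, at 5.79-fold. All 14 rose when adjusted over the list alone, and 5 of them also belong to the interferon gamma response list. B2m, the light chain of MHC class I, differed by 0.71 (SE 0.14, adjusted p = 0.227) and the heavy chain gene H2-K1 by 1.66 (SE 0.37, adjusted p = 0.335), and both missed the threshold. The MHC class II list had a median of 0.86 (0.455 without alopecic replicate 1), 0 of 12 genes past the threshold and 1 when adjusted over the list alone (adjusted p = 0.507 with an estimated correlation). H2-Aa and H2-Eb1 differed by 0.60 (SE 0.33) and 0.53 (SE 0.41). The list of interferons and their receptors was not shifted (median -0.07, mean 0.24, camera direction up, adjusted p = 0.706), with Ifng the 1 of 9 measured genes that rose.

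**Figure D3:**
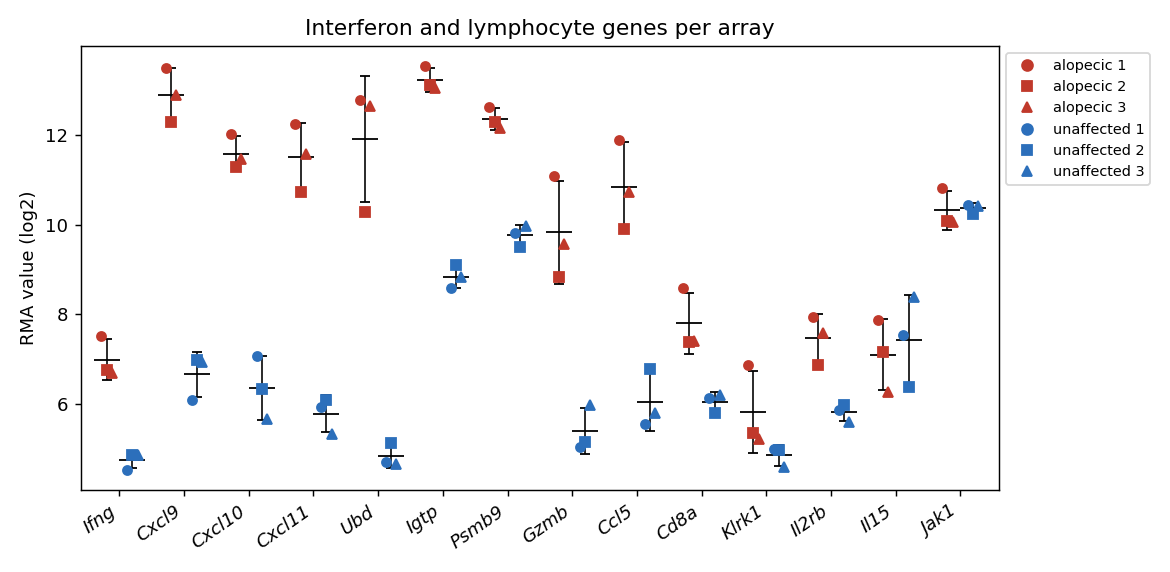
Log2 RMA values, on the y axis, of 14 interferon and lymphocyte genes, on the x axis, with 1 point per array and the mean and SD of each group of 3 arrays as bars. The groups do not overlap for Ifng, the chemokines, Ubd, Igtp, Psmb9, Gzmb, Ccl5, Cd8a, Klrk1 and Il2rb, and they overlap for Il15 and Jak1; Gzmb, Ccl5, Cd8a, Klrk1 and Il2rb did not pass the test over all genes.

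Genes of cytotoxic lymphocytes were higher in alopecic skin as a list, but no single member passed over all genes tested. Of the 22 measured genes 18 rose when adjusted over the list alone, and the median log2 difference was 1.55, or 2.93-fold (camera adjusted p = 4.11e-21, adjusted p = 0.206 with an estimated correlation, fry adjusted p = 0.0375). The chemokine Ccl5 differed by 4.80 (SE 0.58, adjusted p = 0.0599) and the protease granzyme B, Gzmb, by 4.44 (SE 0.61, adjusted p = 0.0843). Cd8a, the co-receptor of cytotoxic T cells, differed by 1.76 (SE 0.36, adjusted p = 0.266), Ctsw by 1.58 (SE 0.41), Klrk1, which encodes the receptor NKG2D, by 0.96 (SE 0.46, adjusted p = 0.779) and Prf1, perforin, by 0.69 (SE 0.25, adjusted p = 0.632). The T cell list had a median of 0.76, with 0 of 17 genes past the threshold and 7 when adjusted over the list alone (adjusted p = 0.27 with an estimated correlation). Its brightest members, Bcl11b at 0.76 (SE 0.31) and Zap70 at 0.23 (SE 0.29), also missed the threshold. The list of regulatory T cells and T cell inhibitory receptors had a median of 0.59 (0.392 without alopecic replicate 1), with 0 of 13 past the threshold and 4 when adjusted over the list alone (adjusted p = 0.165 with an estimated correlation). Tnfrsf18, which encodes the receptor GITR, differed by 0.71 (SE 0.12, adjusted p = 0.147), and Ikzf2 by -0.24 (SE 0.36, adjusted p = 0.915). Chemokines had a median of 0.76, and 4 of 31 rose, Cxcl9, Cxcl10, Cxcl11 and Cx3cl1, the last by 2.55-fold (SE of the log2 difference 0.12), while 10 rose when adjusted over the list alone (adjusted p = 0.166 with an estimated correlation). The 3 other probe sets of Cx3cl1 differed by -0.10, 0.12 and 0.23, with unadjusted limma p of 0.585, 0.635 and 0.166.

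Myeloid lists were shifted by camera, but not in each set of arrays. The macrophage and monocyte list had a median of 0.45, with 0 of 20 genes past either threshold (adjusted p = 0.731 with an estimated correlation). Csf1r differed by 0.10 (SE 0.41) and Lyz2 by 0.35 (SE 0.63). In unaffected replicate 3 the genes of this list lay a median of 1.04 below the mean of the other unaffected arrays. The median was 0.901 without alopecic replicate 2 and 0.796 without unaffected replicate 2, and the call was lost without alopecic replicate 1 (median 0.26, camera adjusted p = 0.257) and without unaffected replicate 3 (median 0.239, camera adjusted p = 0.0721), as it was with genes below the median mean left out (camera adjusted p = 0.239). The dendritic and Langerhans cell list had a median of 0.29, with 0 of 15 genes past the threshold and 1 when adjusted over the list alone (adjusted p = 0.715 with an estimated correlation). Fscn1 differed by 1.27 (SE 0.51) and Clec10a by 0.45 (SE 0.61). Its median was 0.578 without unaffected replicate 2, and its call was lost without alopecic replicate 1 (camera adjusted p = 0.263), unaffected replicate 1 (0.0554) or unaffected replicate 3 (0.173), on ranks (0.081) and with genes below the median mean left out (0.638). Lists of B and plasma cells (median 0.02, 14 genes), neutrophils (0.02, 14 genes) and mast cells (-0.13, 13 genes) were not shifted, with camera adjusted p of 0.65, 0.844 and 0.656. The mast cell list was called as lower without alopecic replicate 1 (median -0.332, camera adjusted p = 0.0152). None of the members of these lists rose or fell; examples are Ighm at -0.06 (SE 0.49), Il1b at 0.48 (SE 0.35) and Cpa3 at -0.66 (SE 1.40).

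Cytokines that signal through the common gamma chain, their receptors and the JAK and STAT family were examined because cytotoxic lymphocytes respond to such cytokines through these kinases. The cytokine and receptor list had a median of 0.49 (0.231 without alopecic replicate 1 and 0.244 without unaffected replicate 2), with 0 of 13 genes past the threshold and 3 when adjusted over the list alone (adjusted p = 0.165 with an estimated correlation, fry adjusted p = 0.0292). The receptor chain Il2rb differed by 1.65 (SE 0.29, adjusted p = 0.177), Il4ra by 1.36 (SE 0.43), Il15ra by 0.49 (SE 0.39) and the cytokine Il15 by -0.33 (SE 0.62, adjusted p = 0.934). The JAK and STAT list had a median of 0.41 (0.275 without unaffected replicate 1), with 0 of 14 genes past the threshold and 1 when adjusted over the list alone (adjusted p = 0.318 with an estimated correlation). Its camera call was lost with genes below the median mean left out (adjusted p = 0.0894). Jak3, the kinase bound to the common gamma chain, differed by 0.48 (SE 0.13, adjusted p = 0.474), Jak2 by 0.33 (SE 0.17), Stat3 by 0.55 (SE 0.26) and Jak1 by -0.05 (SE 0.23). Of the ligands of NKG2D 2 were measured, H60c at 0.46 (SE 0.40) and Ulbp1 at 0.05 (SE 0.11), and neither passed the test.

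Genes of the hair shaft and its sheath did not pass the test over 6 arrays, and their levels spread widely in unaffected skin. Krt33a, a hair shaft keratin, had a log2 value of 12.22 ± 0.40 in alopecic skin and 11.13 ± 5.23 in unaffected skin (SD, n = 3 each), where unaffected replicates 1, 2 and 3 stood at 13.88, 14.42 and 5.09. The lists of hair shaft keratins (12 genes, median 0.01, camera direction down), keratin-associated proteins (33 genes, median -0.23) and the inner root sheath and companion layer (16 genes, median 1.11) had camera adjusted p of 0.919, 0.65 and 0.945, and 0 members rose or fell. Further members were Krt31 at 0.36 (SE 2.05), Krtap8-1 at 1.34 (SE 2.13), Krtap22-2 at 0.67 (SE 2.16), Krt25 at 2.36 (SE 2.33), Krt71 at 1.37 (SE 2.38) and Prr9 at 1.27 (SE 1.99). In unaffected replicate 3 the genes of these lists lay a median of 6.93, 8.10 and 7.94 log2 units below the mean of unaffected replicates 1 and 2, that is 122-fold, 275-fold and 246-fold lower. There Krt33a, Krt31, Krt25 and Krt71 lay below the array median of 6.15, and Krtap8-1, Krtap22-2 and Prr9 above it. As several of these signals were dim, the folds are not exact ratios.

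Without unaffected replicate 3, an array doubted after the data were seen, these lists were lower in alopecic skin. The median log2 difference was then -1.99 for hair shaft keratins, -2.90 for keratin-associated proteins and -1.37 for the inner root sheath and companion layer, or 3.97-fold, 7.44-fold and 2.59-fold lower, with all 12, 33 and 16 genes lower. Camera called each of them in those 5 arrays (adjusted p = 1.91e-10, 3.65e-27 and 8.12e-13), and none passed there with an estimated correlation (adjusted p = 0.28 for each). When each array was left out in turn, the medians ran from -1.99 to 1.298, from -2.896 to 1.508 and from -1.372 to 2.526. Leaving out any other single array gave no camera call for these lists. With all 6 arrays and the hair shaft keratin mean as a covariate, also chosen after seeing the data, the inner root sheath and companion layer list was called as higher (median 0.968, camera adjusted p = 0.00688). That fit compares the groups at an equal level of hair shaft keratins, and both lists were far lower in unaffected replicate 3. It therefore does not show that the sheath list itself was higher in alopecic skin. In the 5 arrays without unaffected replicate 3 and with no covariate, 34 genes rose and 5 fell, and 30 of these 39 were among the 50 genes changed over 6 arrays. The 5 that fell in those 5 arrays, named after their values were seen, were the keratin-associated protein genes Krtap17-1, Krtap10-4, Krtap5-5 and Krtap28-13, and the transcription factor gene Bhlha9, with log2 differences between -2.99 and -2.11.

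**Figure D4:**
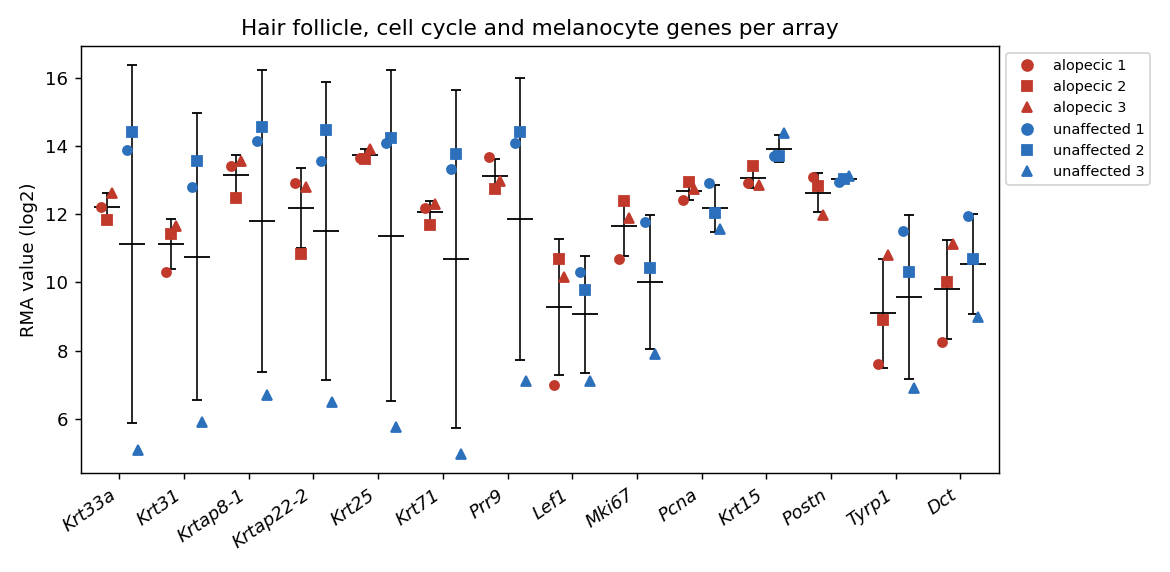
Log2 RMA values, on the y axis, of 14 hair follicle, cell cycle and melanocyte genes, on the x axis, with 1 point per array and the mean and SD of each group of 3 arrays as bars. Krt33a stands at 5.09 in unaffected replicate 3 and between 11.82 and 14.42 in the other 5 arrays.

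The cell cycle list was higher in alopecic skin, with a median of 1.30, or 2.45-fold, and all 28 genes higher, but 0 passed over all genes or over the list alone (camera adjusted p = 1.66e-07, adjusted p = 0.704 with an estimated correlation). Mki67, a marker of dividing cells, differed by 1.62 (SE 1.03) and Pcna, the sliding clamp of DNA polymerase, by 0.51 (SE 0.36). In unaffected replicate 3 the 28 genes lay a median of 2.51 below unaffected replicates 1 and 2; without that array the median was 0.459 (camera adjusted p = 0.00975, adjusted p = 0.762 with an estimated correlation), and without unaffected replicate 1 it was 2.09. The hair follicle stem cell list was lower, with a median of -0.35 and 0 of 19 genes past either threshold (adjusted p = 0.317 with an estimated correlation). Krt15, a keratin of the bulge, differed by -0.86 (SE 0.25, adjusted p = 0.533) and Postn by -0.40 (SE 0.29). The call was lost without alopecic replicate 1 (median -0.21, camera adjusted p = 0.0519). Lists of hair matrix and precortex signalling (26 genes, median 0.14, camera direction down), the dermal papilla (19 genes, median near 0 at -0.00035, mean 0.06) and melanocytes (16 genes, median -0.47) were not shifted, with camera adjusted p of 0.844, 0.844 and 0.156. Among their members, Dsc3 differed by 0.11 (SE 0.15), Ptch1 by 0.14 (SE 0.63), Lef1 by 0.22 (SE 1.26), Sostdc1 by 0.61 (SE 0.32), Igfbp3 by -0.77 (SE 0.37), Tyrp1 by -0.48 (SE 1.38), Dct by -0.74 (SE 0.99) and Rab38 by 0.37 (SE 0.23). Without unaffected replicate 3 the hair matrix list was lower (median -0.674, camera adjusted p = 0.00202), as was the melanocyte list (median -1.42, camera adjusted p = 6.21e-05), and the latter was also called without alopecic replicate 3 (median -1.19, camera adjusted p = 0.00483). With an estimated correlation these calls were lost, with adjusted p of 0.626 for the hair matrix list and of 0.426 and 0.702 for the melanocyte list. When each array was left out in turn, the medians ran from -0.6745 to 0.4486 for the hair matrix list and from -1.416 to 0.4457 for the melanocyte list.

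Among the other tissues of skin, nerve and fat lists were lower and the hypoxia list was higher. The Schwann cell and nerve list had a median of -0.57, with all 10 genes lower and 0 past either threshold (adjusted p = 0.307 with an estimated correlation); the median was -0.364 without alopecic replicate 1 and -0.337 without unaffected replicate 3. The myelin gene Mbp differed by -1.51 (SE 0.92) and Pmp22 by -0.71 (SE 0.34), and Mbp stood at 12.44 in unaffected replicate 3 against 8.54 to 9.19 in the other arrays. The adipocyte list had a median of -0.59 with 0 of 14 past either threshold (adjusted p = 0.704 with an estimated correlation), and its call was lost without alopecic replicate 3 (median -0.203, camera adjusted p = 0.278), unaffected replicate 1 (0.134) or unaffected replicate 2 (median -0.121, camera adjusted p = 0.307), and with arrays centred on the median (0.0582). Fabp4 differed by -0.42 (SE 0.29) and Car3 by -0.25 (SE 0.20). The hypoxia and heat shock list had a median of 0.16, with 1 of 16 past the threshold, the carbonic anhydrase Car9 at 2.98-fold (adjusted p = 0.0158), and 3 when adjusted over the list alone (adjusted p = 0.243 with an estimated correlation). Its median was 0.0886 without alopecic replicate 3, 0.274 without unaffected replicate 2 and 0.0831 without unaffected replicate 3. Its call was lost without alopecic replicate 1 (median 0.287, camera adjusted p = 0.0571) and without unaffected replicate 1 (median 0.273, camera adjusted p = 0.0554), on ranks (0.0807) and with genes below the median mean left out (0.239).

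The remaining lists were not shifted over 6 arrays, and none of their members rose or fell over all genes tested. Epidermal differentiation had a median of -0.20 and a mean of 0.03 over 27 genes (camera adjusted p = 0.844), with Krt10 at -0.30 (SE 0.33) and Sbsn at -0.20 (SE 0.22). Epidermal stress and barrier repair had a median of 0.31 over 28 genes (adjusted p = 0.11), with Krt6a at 0.47 (SE 0.62) and Krt17 at 0.91 (SE 0.46). Sebaceous gland genes had a median of 0.45 over 16 genes (adjusted p = 0.65), with Scd1 at 0.64 (SE 0.35) and Mgst1 at 0.64 (SE 0.63). Fibroblast and dermal matrix genes had a median of -0.05 over 19 genes (adjusted p = 0.597), with Col1a2 at -0.09 (SE 0.58) and Dcn at -0.47 (SE 0.25). Endothelial genes had a median of -0.21 and a mean of 0.05 over 17 genes (adjusted p = 0.65), with Flt1 at 1.59 (SE 0.57, adjusted p = 0.64) and Egfl7 at -0.21 (SE 0.42). When adjusted over the list alone, 1 endothelial gene rose. Skeletal muscle genes had a median of -0.05 over 24 genes (adjusted p = 0.839), with Acta1 at 0.10 (SE 0.52) and Myh4 at 0.20 (SE 0.51). Erythroid genes had a median of -0.15 over 5 genes (adjusted p = 0.644), with Slc4a1 at -0.18 (SE 0.97). The circadian clock list had a median of -0.67 over 16 genes (adjusted p = 0.149), with Tef at -0.91 (SE 0.65) and Nr1d2 at -0.55 (SE 0.41). Immediate early genes had a median of -0.15 over 14 genes with a camera direction of up (adjusted p = 0.898), with Egr1 at 0.09 (SE 0.58) and Dusp1 at 0.20 (SE 0.99). The clock list was called as lower with genes below the median mean left out (adjusted p = 0.0265) and with the hair shaft keratin covariate (0.0109), while without unaffected replicate 3 its median was -0.15 (0.565). Some of these lists passed camera when 1 array was left out, and none of them did so with an estimated correlation. Without unaffected replicate 3 the median was -0.492 for epidermal differentiation, -0.175 for sebaceous gland, -0.355 for fibroblast, 0.787 for skeletal muscle and 0.498 for immediate early genes (camera adjusted p = 0.00975, 0.00975, 0.0302, 0.00318 and 0.000405). Without unaffected replicate 2 it was 0.79 for epidermal stress and -1.06 for skeletal muscle (0.00323 and 3.68e-07), and without unaffected replicate 1 it was 0.872 for sebaceous gland and -1.01 for clock genes (0.0136 and 0.00388). Without alopecic replicate 1 it was -0.484 for epidermal differentiation and -0.294 for fibroblast genes (0.0152 and 0.000796), and without alopecic replicate 2 it was 1.02 for epidermal stress genes (0.000143). Unaffected replicate 3 lay a median of 2.59 above unaffected replicates 1 and 2 in skeletal muscle genes, 2.27 above in immediate early genes, 1.64 above in clock genes, 1.71 below in sebaceous gland genes and 1.12 below in epidermal differentiation genes.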

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

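The counts over other splits of the arrays, the test of each probe set, the fits with 1 array left out, camera with an estimated correlation over 6 arrays and quantile normalization were set before the data were examined. The use of the values without unaffected replicate 3 to weigh an explanation and the tests of muscle, matched lists, RNA degradation, epithelium, a swap, the growth phase and an estimated correlation without that array were chosen after the results had been seen. Probe sets with no single gene symbol, which the gene comparison did not use, also held a signal. When each of 45037 probe sets was tested on its own with limma, 64 passed an adjusted p of 0.05. Among these, 6 with no symbol in the annotation table and 3 with several symbols were higher in alopecic than in unaffected skin, with log2 differences between 2.94 and 5.08.

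The interferon gamma response list was higher in alopecic skin by a median of 3.07, and a hair follicle state peculiar to unaffected replicate 3 is argued against as the cause, because the median was 3.00 without that array and all 27 genes were still higher. A different share of muscle in the biopsies is argued against, since unaffected arrays spanned muscle list medians from -1.92 to 1.76, beyond the -0.794 to 0.796 of alopecic arrays, while their interferon gamma response medians differed by at most 0.127. The scaling between arrays, which moves genes of one level alike, is argued against because 10000 random lists of other genes matched on mean expression had medians of at most 0.292, whereas quantile normalization moved no gene difference by more than 0.112 and decided nothing. Of 10 splits of the 6 arrays into 3 and 3, only the real one gave 50 changed genes, and the highest other gave 0. These splits are too few for a share under 0.05. By camera with the preset correlation, 7 splits, the real one among them, gave at least its 17 shifted lists, and the highest other gave 24. That count of lists was therefore not particular to the real grouping. By fry the real split gave 7 lists and the highest other 2. The median difference of the interferon gamma response list was 3.07 in the real split and at most 1.4 in the others. The difference in phenotype that the design names stays open as a hypothesis, and any batch that follows the groups is not given in the sources used here.

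Unaffected replicate 3 stood apart from the other arrays in genes of the growing hair follicle. RNA degradation with loss of 5' ends is argued against by its 3' minus 5' beta-actin difference of 0.386, below those of the other 5 arrays, and by a Gapdh difference of 0.311 against up to 0.517 elsewhere, but its 18S ribosomal control probe sets were all lower, at 11.8 against 12.87 to 13.72 (3' end), 12.12 against 13.78 to 14.27 (middle) and 12.81 against 14.1 to 14.35 (5' end), so other differences in RNA quality stay open. A lower share of epithelium is argued against as the whole cause of the hair shaft keratin difference of -6.93 by the hair follicle stem cell list, which was 0.204 higher than in the other unaffected arrays (SD 0.819 over its genes), and a swap with an alopecic sample by its interferon gamma response median of -1.66, among the unaffected arrays. A candidate explanation, as a hypothesis found in the same data, is that its follicles were out of the growth phase, since hair shaft keratins (-6.93), the inner root sheath (-7.94) and cell cycle genes (-2.51) were all lower there than in the other unaffected arrays. Whether a smaller loss of epithelium or more muscle also took part cannot be told apart, since epidermal differentiation (-1.12) and sebaceous gland (-1.71) genes were lower and skeletal muscle genes (2.59) higher there while stem cell genes were not lower, and age, body site and hair cycle stage are not given in the sources used here.

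The cell cycle list was higher in alopecic skin by a median of 1.30 over 6 arrays. Without unaffected replicate 3 the median was 0.459, with all 28 genes still higher on average and a camera adjusted p of 0.00975. In 0 of these 28 genes did all alopecic arrays lie above both remaining unaffected arrays. A part of the difference therefore came with unaffected replicate 3. Whether the rest belongs to the alopecic phenotype or to the hair follicle state of single mice cannot be told apart with 3 arrays against 2, and with an estimated correlation the adjusted p was 0.704 over 6 arrays and 0.762 without that array.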

How the results depend on the processing

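The count of 50 changed genes (48 higher, 2 lower) stayed within 1.5 times, at 45 to 69, under an intensity trend, robust fitting, quantile normalization, centring, filters on dim genes, other choices of probe sets, a 2-fold minimum and, chosen after seeing the data, the hair shaft keratin mean as a covariate. The plain per-gene t-test gave 0 after adjustment in total and in each direction, with 1234 genes at an unadjusted p under 0.05. Array weights gave 139 genes, 126 higher and 13 lower. Lower genes numbered 1 with robust fitting, with every probe set tested and without probe sets of suffix _x_at or _s_at, and 13 with the covariate. Leaving out each array gave 4 to 39 changed genes, 4 to 34 higher and 0 to 5 lower; fewer arrays leave fewer degrees of freedom. With the replicate number as a block, limma gave 0 changed genes, 0 higher and 0 lower (873 at an unadjusted p under 0.05), and 17 lists. Arrays with the same number correlated at -0.132, -0.197 and -0.33 in their deviations from the group means, which gave no sign of a pairing. With 3 arrays per group, and 42.2% of the squared deviations in unaffected replicate 3, these correlations cannot exclude one. Shifted lists numbered 0 with an estimated correlation over 6 arrays (0 higher, 0 lower), 7 by fry (7 higher, 0 lower) and otherwise 13 to 25; higher lists numbered 9 without genes below the median mean, and the cause was not tested. With an estimated correlation and each array left out, chosen after seeing the data, 0 or 1 list passed (0 or 1 higher, 0 lower). Leaving out each array gave 16 to 25 lists, 11 to 15 higher and 3 to 11 lower. Without unaffected replicate 3 the direction turned, with a camera call, for the inner root sheath and companion layer, sebaceous gland and skeletal muscle lists. In these lists that array lay a median of 7.94 and 1.71 below and 2.59 above unaffected replicates 1 and 2. Leaving it out therefore moved the unaffected mean, while what set that array apart stays open. With each array left out the medians of these lists ran from -1.372 to 2.526, from -0.1751 to 0.8721 and from -1.064 to 0.7867. Over all alternatives, values of the 98 named genes kept their direction and side of the threshold in 1797 cases, lost the call in 134, gained it in 8 and reversed in 0; for 36 lists the numbers were 584, 146, 19 and 3. Sign changes with neither value called, 75 for genes and 79 for lists, are counted among those kept. Most of the 98 named genes were not called over 6 arrays, and 17 of the 36 lists were called. Only called results could lose a call, so most kept cases are results that stayed uncalled. The number kept therefore does not show that the calls are stable. The mean correlation between groups was 0.8309 over the genes above the median mean and 0.9466 to 0.9691 with each array left out. With each array left out, the alopecic minus unaffected difference of the 3' minus 5' measure ran from 0.0969 to 0.529 for beta-actin. For Gapdh it ran from 0.075 to 0.353. Signal near background limits dim genes such as Klrk1, and in simulated data 34.3% of genes changed 2-fold were recovered.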

Other observations

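The genes of this part, apart from Ighm, were chosen after their values were seen, and no test was added for them. Melanocyte genes were low in alopecic replicate 1 and unaffected replicate 3. The list median, relative to each gene's mean over 6 arrays, was -1.40 and -1.58 in these arrays, against -0.13 and 0.59 in the other alopecic and 1.97 and 0.64 in the other unaffected arrays. Mlana, a melanosome protein, stood at 4.72 and 5.10 in these arrays and between 8.96 and 10.78 in the other 4. Mitf, a transcription factor of melanocytes that other cells also express, followed the groups more closely, with a log2 difference of -1.29 (adjusted p = 0.309) and all alopecic arrays below all unaffected arrays. Fgf18, a growth factor gene placed in the stem cell list, had log2 values of 5.25, 5.64 and 5.19 in alopecic and 7.06, 7.94 and 10.41 in unaffected skin, a difference of -3.11 that missed the threshold (adjusted p = 0.485). Bmp6 in the same list differed by -1.20 (adjusted p = 0.309). Jchain, the joining chain of secreted antibodies, differed by 3.65 (adjusted p = 0.454), with 8.03 to 10.35 in alopecic and 4.79 to 7.51 in unaffected skin. Igha, an antibody heavy chain gene, differed by 3.51, or 11.4-fold (adjusted p = 0.54), while Ighm differed by -0.06 (adjusted p = 0.983). The values of Igha ran from 9.87 to 12.36 in alopecic and from 6.68 to 9.81 in unaffected skin, so the groups only just did not overlap.

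Unaffected replicate 3 also held other levels of clock and immediate early genes than the remaining arrays. Dbp, an output gene of the circadian clock, stood at 12.26 there and between 8.23 and 10.32 in the other 5 arrays. Per2 stood at 8.60 against 5.75 to 6.78 and Nr1d1 at 9.33 against 7.06 to 7.52, whereas Arntl, which encodes the clock activator BMAL1, stood at 7.79 against 8.33 to 9.38. Among immediate early genes, Nr4a1 stood at 13.08 against 8.81 to 11.56 and Atf3 at 12.67 against 7.89 to 11.08. The time of day and the order of sampling are not given in the sources used here. Skeletal muscle genes were lowest in unaffected replicate 2, with a list median of -1.92, and highest in unaffected replicate 3, at 1.76.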
